A study of Locusta migratoria with 4 samples.

How the data were processed

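Small RNA of 18 to 30 nt was recovered from a gel, ligated to adapters, amplified and sequenced on an Illumina instrument, per the labels' protocols. The values used are whole-number counts per miRNA that the authors deposited in 1 table, with 1 column per time per the file headers. The software for mapping, for predicting miRNAs and for predicting targets, and the genome, are not given in the sources used here. The table also gave numbers per small RNA class and predicted targets. Whether class numbers are reads or distinct sequences is not stated, so they serve only for shares.

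The table had 789 rows. In 5 cases a predicted miRNA had the sequence of a named one, and the named row was kept, which left 784 features. Counts were divided by the sum over features in that library and expressed as RPM, the usual scaled read count. These sums cover listed miRNAs and not the whole sequenced library. The smallest count above 0 of a predicted miRNA was 5, so a listed 0 can be a feature left off that library's list. This was seen after the comparisons were fixed, and calls are therefore split by whether both libraries list the feature.

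With 1 library per group no test across groups was possible and no p-value is given. A feature was called by size: a ratio of at least 2 or at most 0.5, a 95% exact conditional binomial (Clopper-Pearson) interval excluding 1, and at least 50 counts in one of the libraries compared. For the ratio bound and the ranking a listed 0 stood for 3 reads, while the interval took it as 0. A feature listed at 0 in one library with at least 50 counts in the other is therefore always called. Reads amplified by PCR are not independent molecules, so intervals cover counting error only. The total was smallest at 24 h, 173617.

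The features named were fixed by rule before the data were examined: the 10 most abundant by mean RPM, up to 12 greatest rises and 12 greatest falls among called features for each comparison with 0 h, up to 12 per direction at all 3 times, and members of fixed lists with at least 50 counts. Rises and falls listed in both libraries are given with ratios and the others with counts. The lists covered immune regulators, ecdysone and moulting, miRNA clusters and families, metabolism, growth, and muscle, nervous system, ovary, epithelium, plant and vertebrate markers. List medians used features listed in both libraries, and percentiles came from 10000 random lists matched on mean expression in 5 bins.

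Conserved families were assigned by an identical seed, positions 2 to 8, and at most 6 mismatches to 65 reference sequences written from general knowledge, not from a supplied database. The reference matched 59 features, against a mean of 0.3 for 20 shuffled reference sets. Similar sequences were linked at up to 5 mismatches over at least 19 nt, and end variants by an identical overlap of at least 18 nt.

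The calling rule was checked on simulated counts with 200 changed features. For 12 h against 0 h with counting error alone, it called 15 of 15 tested features with a ratio of 4 and 17 of 17 with a ratio of 3 among 784 features. With an assumed CV of 0.2 it called 4 of 8 tested features with a ratio of 0.333 and 2 of 99 unchanged ones in that comparison. With that CV it called 4 of 85 unchanged features for 24 h against 0 h and 3 of 82 for 36 h against 0 h. The simulated counts do not model features left off a list, so these rates do not cover calls that rest on a listed 0. Unchanged libraries were simulated 200 times against the shared 0 h library.

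Alternatives were TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), totals without the 10 most abundant features, minima of 10, 200 or no counts, ratios of 1.5 and 4, intervals widened by a CV of 0.2 or 0.4, every row as a feature, and sums over families. Added after seeing the data were calls limited to features listed in both libraries, merged end variants, totals and shares without novel_mir_174, list medians with listed zeros set at 3 reads and correlations over features listed in all 4 libraries. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib and R 4.3.3.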

Results

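Small RNA was sequenced from the migratory locust, Locusta migratoria, before and after injection of the insect-killing fungus Metarhizium robertsii. There were 4 libraries, with 1 library for each of 4 groups: uninfected locusts at 0 h and infected locusts at 12, 24 and 36 h. Per the labels, locusts were of instar 3, those of the infected groups each received 5 μl of spore suspension, and abdomens were collected, although the tissue label reads whole body. Each sample is described as holding 3 replications, which were deposited as 1 column per time. The miRNA counts summed to 453615 at 0 h, 500419 at 12 h, 173617 at 24 h and 286368 at 36 h. No difference below has a replicate check, and every interval is a 95% interval that covers counting error only.

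The table held 784 distinct mature sequences, of which 13 carried locust miRNA names (prefix lmi) and 771 carried the authors' names for predicted miRNAs (prefix novel_mir). By sequence, 51 of the predicted miRNAs matched 34 conserved insect families and are called by that family with the ending "like". The libraries listed 249 predicted miRNAs at 0 h, 397 at 12 h, 306 at 24 h and 329 at 36 h. Only 81 features were listed in all 4 libraries, and 508 were listed in 1 library, with a median count of 7. The smallest count above 0 of a predicted miRNA was 5, so a listed 0 is not a measured absence, and no ratio of a single feature is given against one. Calls, correlations, and list medians where stated, include listed zeros set at 3 reads. A median over 2 members, of which 1 is listed in both libraries, then depends on that setting.

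The most abundant miRNA was lmi-miR-281-5p, which made up 32.2% of the counts at 0 h (95% Clopper-Pearson interval 32.1 to 32.4), 49.6% at 12 h (49.4 to 49.7), 46.6% at 24 h (46.4 to 46.9) and 43.6% at 36 h (43.4 to 43.8). With novel_mir_174 left out of the totals these shares were 42.0%, 50.2%, 48.2% and 44.5%. The second was lmi-miR-10-5p, from the Hox gene cluster of insects, with 8.93%, 9.28%, 8.64% and 12.7% at 0, 12, 24 and 36 h. Next came novel_mir_174, at 23.2% of counts at 0 h (23.1 to 23.3) and 1.28% at 12 h, 3.27% at 24 h and 2.10% at 36 h. The other features among the 10 most abundant were novel_mir_57, novel_mir_240 (miR-31-like), novel_mir_84 (like bantam, a growth regulator in Drosophila), novel_mir_151 (miR-184-like), novel_mir_27 (miR-750-like), lmi-miR-276-3p and novel_mir_230 (miR-9-like). Together these 10 features held 85.9% of counts at 0 h, 81.0% at 12 h, 81.7% at 24 h and 81.6% at 36 h. Apart from novel_mir_174, none of the 10 met the size rule at any infected time.

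**Figure D1:**
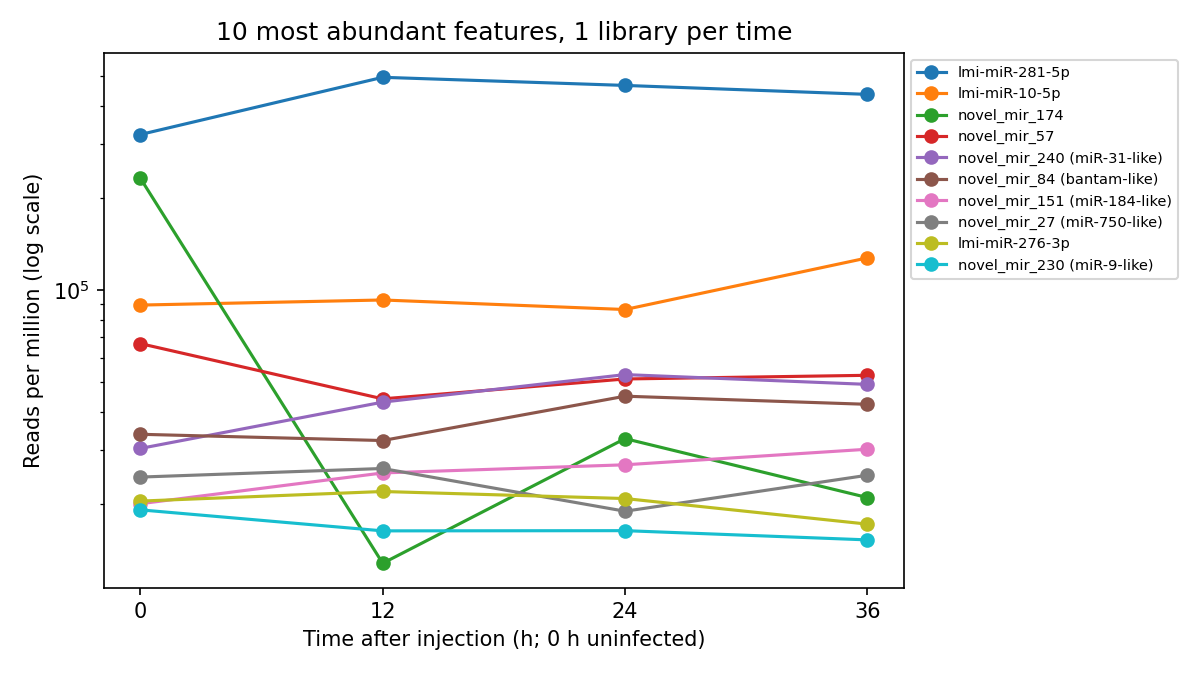
RPM (log scale) of the 10 most abundant features against time in hours, with 1 library per time and 0 h uninfected. Each line is a feature, and novel_mir_174 went from 231961 RPM at 0 h to 12787 at 12 h.

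Features with sequences of known or conserved miRNAs held 65.3% of counts at 0 h, 84.1% at 12 h, 80.8% at 24 h and 84.5% at 36 h. With novel_mir_174 left out they held 85.0%, 85.2%, 83.5% and 86.3%. Sequences of 20 nt, the length of novel_mir_174, made up 25.7%, 4.64%, 5.49% and 5.25% of counts in the same order, and 3.32%, 3.40%, 2.30% and 3.22% without it. Sequences of 22 nt made up 56.8%, 75.2%, 71.9% and 73.0%, and without it 74.0%, 76.2%, 74.3% and 74.6%. A first base of U was carried by 57.8% of counts at 0 h, 36.5% at 12 h, 39.7% at 24 h and 42.2% at 36 h, and by 45.1%, 35.7%, 37.7% and 41.0% without novel_mir_174.

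At 12 h, the greatest rises among features listed in both libraries were those of predicted miRNAs with no conserved match. Counts of novel_mir_181 went from 6 to 2177, a ratio of 329 (151 to 897) in normalised counts (RPM). The ratio was 291 (141 to 725) for novel_mir_160, 220 (101 to 600) for novel_mir_184 and 120 (66.7 to 240) for novel_mir_182. Ratios of 52.3 for novel_mir_159, 22.6 for novel_mir_183, 21.2 for novel_mir_186 and 17.6 for novel_mir_216 followed. The greatest falls were those of novel_mir_174, at a ratio of 0.0551 (0.0537 to 0.0565), and novel_mir_158, at 0.101 (0.0419 to 0.209). The miR-315-like novel_mir_154 fell from 2327 to 574 counts, a ratio of 0.224 (0.204 to 0.245).

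At 12 h, 60 features were higher and 18 lower than at 0 h among 139 tested, by a ratio of at least 2 or at most 0.5. Of these, 11 of the higher and 12 of the lower features were listed in both libraries, and 61 features listed in both met neither bound. The other 49 higher and 6 lower features were listed at 0 in 1 of the libraries. The rule calls every tested feature of that kind, so these calls do not measure a change. Features listed at 0 in the 0 h library included novel_mir_511 (4166 counts at 12 h), novel_mir_517 (2663), novel_mir_391 (1223), novel_mir_422 (840), novel_mir_429 (833), novel_mir_371 (801), novel_mir_396 (754), novel_mir_294 (618) and novel_mir_426 (617). Of these, novel_mir_511 was listed at 0 at 24 h and had 1896 counts at 36 h, and novel_mir_517 was listed only at 12 h. Features listed at 0 in the 12 h library included novel_mir_214 (429 counts at 0 h), novel_mir_250 (199), novel_mir_7 (116), novel_mir_193 (63), novel_mir_234 (miR-927-like, 51) and novel_mir_136 (miR-278-like, 50). Of these, 4 had a variant with other ends listed in the 12 h library. Merging the variants, with the greatest count per library, gave ratios of 0.797 (0.647 to 0.982) for novel_mir_250 and 1.60 (1.12 to 2.31) for novel_mir_136, which ended both calls, and 4.58 (3.48 to 6.10) for novel_mir_193, which turned its direction. The merged ratio of novel_mir_234 was 0.267 (0.139 to 0.482). Among falls listed in both libraries, novel_mir_90 had a ratio of 0.239, novel_mir_138 of 0.273 and novel_mir_106 of 0.314. With calls limited to features listed in both libraries, 11 were higher and 12 lower.

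At 24 h, the same predicted miRNAs led the rises listed in both libraries. The ratio to 0 h was 341 (156 to 932) for novel_mir_181, 316.9 (153 to 791) for novel_mir_160, 237 (108 to 648) for novel_mir_184 and 136 (75.6 to 275) for novel_mir_182. The star strand lmi-miR-281-3p was also higher, at a ratio of 2.09 (1.62 to 2.69), which was 1.78 with TMM scaling and then missed the bound. Among falls, novel_mir_134 had a ratio of 0.107 (0.0424 to 0.225), novel_mir_174 of 0.141 (0.137 to 0.145) and the miR-315-like novel_mir_154 of 0.164 (0.138 to 0.194). The lmi-miR-8-5p strand fell to a ratio of 0.443 (0.376 to 0.520), while lmi-miR-8-3p had a ratio of 0.837 (0.736 to 0.950).

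At 24 h, 48 features were higher and 30 lower than at 0 h among 123 tested, and 11 and 13 of them were listed in both libraries. The other 37 and 17 rest on a listed 0 and were called by construction. Features at 0 in the 24 h library included novel_mir_237, like let-7, a regulator of developmental timing, with 1664 counts at 0 h, 2254 at 12 h and 1584 at 36 h. Others were novel_mir_64 (611 counts at 0 h), novel_mir_55 (miR-305-like, 289), novel_mir_188 (229) and novel_mir_178 (miR-304-like, 88). Variants of 2 of these with other ends were listed at 24 h, and merging ended both calls: the merged ratio was 0.765 (0.644 to 0.906) for novel_mir_64 and 0.856 (0.650 to 1.12) for novel_mir_188. Among features at 0 in the 0 h library, novel_mir_592 had 1226 counts at 24 h, novel_mir_391 had 505, novel_mir_422 had 453 and novel_mir_429 had 444. Of these, novel_mir_592 was listed only at 24 h. TMM scaling shifted every log2 ratio of this comparison by -0.23.

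At 36 h, novel_mir_160 had a ratio to 0 h of 186 (89.7 to 463), novel_mir_181 of 172 (78.7 to 471), novel_mir_184 of 146 (66.6 to 400) and novel_mir_182 of 39.9 (21.9 to 80.8). The miR-34-like novel_mir_61 had a ratio of 2.14 (1.47 to 3.14) and lmi-miR-281-3p of 2.10 (1.68 to 2.62). With totals that left out the 10 most abundant features, these were 1.65 and 1.61 and missed the bound. The greatest falls listed in both libraries were novel_mir_174 at 0.0904 (0.0881 to 0.0928), novel_mir_154 at 0.148 (0.129 to 0.171), novel_mir_106 at 0.153 (0.0771 to 0.277) and novel_mir_224 at 0.186 (0.0773 to 0.388).

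At 36 h, 41 features were higher and 20 lower than at 0 h among 117 tested, and 11 and 9 of them were listed in both libraries. The other 30 and 11 rest on a listed 0 and were called by construction. Among features at 0 in the 0 h library, novel_mir_511 had 1896 counts at 36 h, novel_mir_691 had 557, novel_mir_371 had 505, novel_mir_391 had 404 and novel_mir_755 had 367. Of these, novel_mir_691 and novel_mir_755 were listed only at 36 h, and novel_mir_511 was listed at 0 at 24 h. Features at 0 in the 36 h library included novel_mir_214, novel_mir_250, novel_mir_199 (141 counts at 0 h), novel_mir_7 and the miR-13-like novel_mir_149 (67 counts at 0 h). Variants of 3 of these with other ends were listed at 36 h, and merging ended the calls: the merged ratio was 1.23 (0.987 to 1.52) for novel_mir_250, 0.966 (0.730 to 1.27) for novel_mir_199 and 0.757 (0.480 to 1.17) for novel_mir_149.

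**Figure D2:**
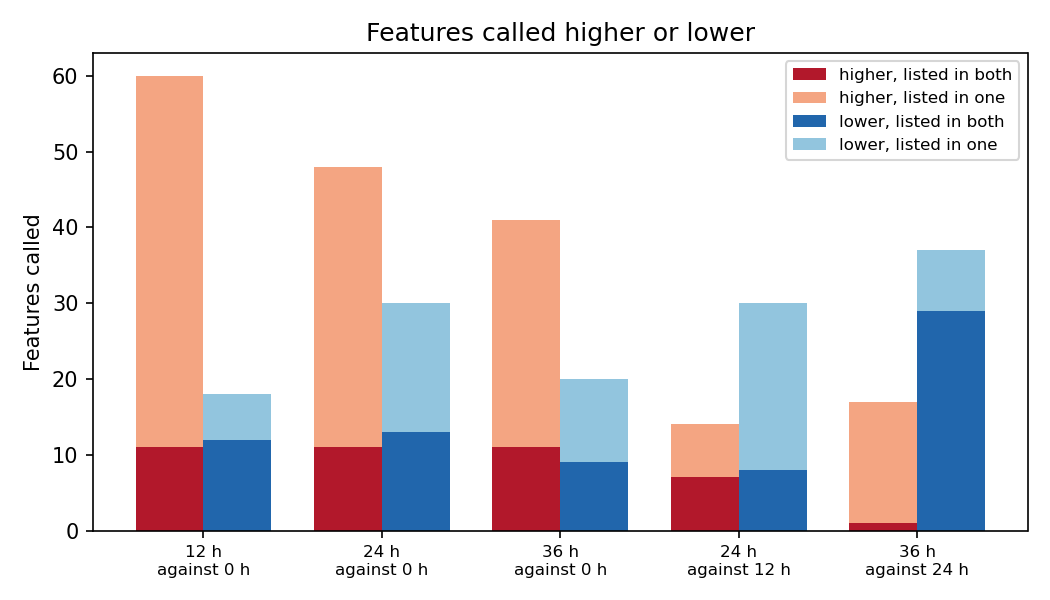
Number of features called higher (red) or lower (blue) in 5 comparisons of 2 libraries each. The dark part of each bar counts features listed in both libraries. The pale part counts those listed in 1 of them, which are called by construction. At 12 h against 0 h these were 11 and 49 for higher features.

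Between 12 h and 24 h, 14 features were higher and 30 lower at 24 h, of which 7 and 8 were listed in both libraries. Which direction held more features depended on the minimum count. With a minimum of 10 counts 74 were higher and 64 lower, and with no minimum 169 and 64. The totals were 173617 at 24 h and 500419 at 12 h, so a listed 0 set at 3 reads is more RPM at 24 h. Low counts against a listed 0 are then called more readily as higher at 24 h than as lower. The counts with these lower minima therefore do not show which direction changed more. The rise with the greatest ratio was that of novel_mir_263, from 6 to 188 counts (ratio 90.3, 40.7 to 249). The miR-14-like novel_mir_248 fell to a ratio of 0.499 (0.462 to 0.540) and the miR-279-like novel_mir_85 to 0.485 (0.424 to 0.553). Both ratios lie near the bound of 0.5 and missed it with other scalings: novel_mir_248 was at 0.501 with median-of-ratios scaling and at 0.519 with totals that left out the 10 most abundant features, and novel_mir_85 was at 0.504 with those totals. Between 24 h and 36 h, 17 features were higher and 37 lower at 36 h, of which 1 and 29 were listed in both libraries. Of those 29 falling features, 17 had been higher than at 0 h at all 3 infected times, among them novel_mir_182 (ratio 0.293, 0.253 to 0.338), novel_mir_159 (0.283, 0.236 to 0.337) and novel_mir_429 (0.300, 0.254 to 0.354). These features of the later comparisons were chosen after their values were seen.

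At all 3 infected times, 27 features were higher and 15 lower than at 0 h, and 7 of each were listed in all 4 libraries. The 27 included novel_mir_391, novel_mir_181, novel_mir_371, novel_mir_160, novel_mir_422, novel_mir_429, novel_mir_184, novel_mir_294, novel_mir_396, novel_mir_426, novel_mir_386 and novel_mir_434. The 15 included novel_mir_214, novel_mir_250, novel_mir_7, novel_mir_193, novel_mir_174, novel_mir_105, novel_mir_138, novel_mir_234, novel_mir_154, novel_mir_106, novel_mir_134 and novel_mir_173. The falls of novel_mir_250 and novel_mir_193 were not kept when end variants were merged: novel_mir_250 then met no bound and novel_mir_193 was higher at all 3 times, at 4.58, 3.15 and 2.89. The variants of these, novel_mir_516 and novel_mir_458, were both among the 27. Unchanged libraries simulated against the same 0 h library gave a mean of 0 in both directions with counting error alone. With an assumed CV of 0.2 the mean was 0.185 higher and 0.1 lower, and the greatest numbers were 4 and 3. The simulation does not model features left off a list, so these values can be set only against the 7 and 7 listed in all 4 libraries. Only 104 features, listed zeros included, were tested at all 3 times. Independent lists as long as those called among these 104 would share 2.10 higher and 0.999 lower features. A feature below the minimum count at 0 h is among the 104 only if it met that minimum at all 3 infected times. This filter itself selects rises shared by all 3 times, so the 27 cannot be judged against 2.10.

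Log2 ratios to 0 h correlated across 158 features between 12 h and 24 h (Pearson r = 0.76), 12 h and 36 h (0.78) and 24 h and 36 h (0.76). Unchanged libraries simulated with a CV of 0.2 gave r of 0.47, 0.49 and 0.46. The covariances were 10.2, 8.78 and 9.33, against simulated covariances of 0.11, 0.11 and 0.11. The observed values include listed zeros set at 3 reads, and features left off a list were not simulated. Over the 66 features listed in all 4 libraries the covariances were 5.90, 4.92 and 5.27 and r was 0.97 in each case. A few features with very large ratios weigh most in these values, such as novel_mir_181, with log2 ratios of 8.36 at 12 h and 8.41 at 24 h. Most tested features listed in both libraries met neither bound: 61 of 84 at 12 h, 45 of 69 at 24 h and 56 of 76 at 36 h. The 3 comparisons share the 0 h library, so part of the excess can come from that shared library, and features are not independent replicates.

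Several of the features higher at all 3 times had similar sequences. With up to 5 mismatches over at least 19 nt, a family of 21 predicted miRNAs, led by novel_mir_184 and novel_mir_426, summed to 99.2 RPM at 0 h, 9870 at 12 h, 12280 at 24 h and 5821 at 36 h, and 9 of its members were among the 27. A family of 5 with novel_mir_391 and novel_mir_159 summed to 30.9, 5993, 6209 and 3104 RPM, with 3 among the 27. A family of 6 with novel_mir_294 and novel_mir_417 was listed at 0 at 0 h and summed to 1916, 3341 and 1072 afterwards, with 2 among the 27. A family of 12 with novel_mir_488 went from 17.6 to 947, 1670 and 377, although 0 of its members were among the 27. A family of 6 with novel_mir_105 went from 293 to 146, 34.6 and 80.3. Members not listed in a library add 0 to these sums, although a listed 0 is not a measured absence. At 0 h the families with novel_mir_184, novel_mir_391 and novel_mir_488 had 3, 1 and 1 members listed, and at 24 h 18, 5 and 7. The family with novel_mir_105 had 3 listed at 0 h and 1 at 24 h. The sums can therefore overstate a rise or fall.

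**Figure D3:**
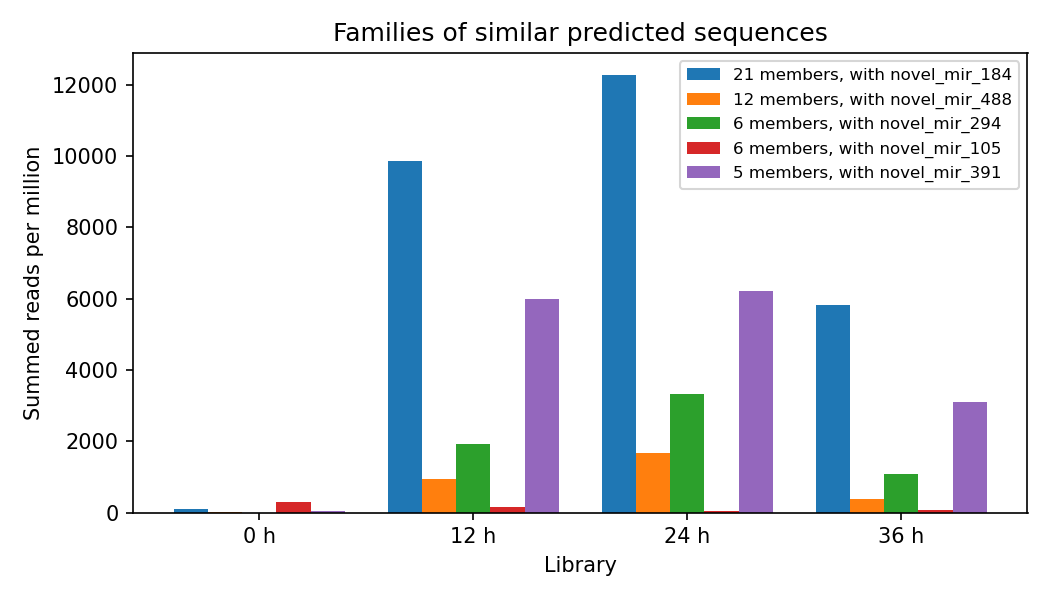
Summed RPM of 5 families of similar predicted sequences in each of the 4 libraries, 1 bar per family. The family of 21 members was at 99.2 at 0 h, with 3 members listed, and 12280 at 24 h, with 18 listed. Members not listed in a library add 0.

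Regulators of Toll, IMD and antimicrobial peptide genes in Drosophila were represented by 4 features. At 12 h none of the 4 met the size rule, with a median log2 ratio of 0.00 (percentile 37.4 of 10000 random lists). At 24 h the 2 members listed in both libraries were lmi-miR-8-5p and lmi-miR-8-3p, the 2 strands of miR-8. The first was lower and the second did not meet the size rule. Their median was -0.72 (percentile 9.38), or -1.94 over all 4 members with listed zeros set at 3 reads. At 36 h the miR-34-like feature was higher and the median was 0.11 (percentile 63.7), or -0.38 with a minimum of 200 counts. The 8 tested features of the ecdysone and moulting list had medians of 0.13 at 12 h and 0.44 at 36 h (percentiles 65.1 and 93.6), and 2 were higher at 36 h. With a minimum of 200 counts the median at 36 h was 0.12. At 24 h the 6 members listed in both libraries had a median of -0.07 (percentile 46.3), -0.26 with that minimum, -0.30 with TMM scaling and -0.55 over 8 members with listed zeros set at 3 reads, with lmi-miR-281-3p higher and lmi-miR-8-5p lower.

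Totals without the 10 most abundant features shifted log2 ratios to 0 h by -0.42 at 12 h, -0.37 at 24 h and -0.38 at 36 h. Totals without novel_mir_174 alone shifted them by -0.36, -0.33 and -0.35. List medians between 0 and the size of such a shift therefore change sign with the scaling. With TMM, the 24 h medians of the miR-9 list, the cluster of miR-2 and miR-13 and the growth list were -0.23, -0.16 and -0.16.

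Of the miRNA clusters, the let-7 complex had medians of 0.19 at 12 h and 0.52 at 36 h (percentiles 57.6 and 88.9), with the miR-100-like novel_mir_238 at a ratio of 1.36 (1.30 to 1.42) at 36 h. At 24 h only novel_mir_238 of that complex was listed in both libraries (log2 ratio 0.11), and the median was -3.81 with the listed 0 of the let-7-like member set at 3 reads. The cluster of miR-12, miR-283 and miR-304 had medians of 0.26, 0.31 and 0.23 at 12, 24 and 36 h, and its miR-304-like member was listed at 0 at 24 h. The miR-9 list had medians of -0.14, 0.00 and 0.27, the miR-279 family -0.16, -0.61 and -0.01, and the cluster of miR-275 and miR-305 -0.04 at 12 h and 0.15 at 36 h. At 24 h the last had 1 member listed in both libraries, at -0.37, and a median of -2.79 with the listed 0 set at 3 reads. The cluster of miR-277 and miR-34 had medians of 0.03 at 12 h and 0.42 at 36 h, the latter -0.26 with a minimum of 200 counts, and the cluster of miR-2 and miR-13 -0.54 at 12 h and 0.07 at 24 h. Single members listed in both libraries stood at -0.22 for the first at 24 h and at -0.46 for the second at 36 h. With listed zeros set at 3 reads the medians were -1.46 and -2.14 there, and -0.29 for the second at 12 h. Single members stood for the miR-263 family (log2 ratios of -0.84, -0.50 and 0.16) and the miR-92 family (-0.39, -0.75 and -0.14).

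The metabolism and fat body list had medians of -0.01, -0.31 and -0.23. Among its members listed in both libraries only lmi-miR-8-5p met the size rule, lower at 24 h. Its miR-305-like novel_mir_55 was listed at 0 at 24 h. The growth and apoptosis list had medians of -0.18, 0.07 and -0.20, with none called among members listed in both. With listed zeros set at 3 reads the growth list had medians of -0.07 at 12 h and -0.33 at 36 h. Epithelial and sensory organ miRNAs had medians of 0.33, 0.39 and 0.59 (percentiles 76.2, 87.4 and 95.9), and none of the 3 met the size rule. Members were the miR-184-like novel_mir_151 and novel_mir_144 and the miR-263-like novel_mir_191. The last had log2 ratios of -0.84, -0.50 and 0.16, so each median is the value of a miR-184-like feature. The muscle list held the miR-133-like novel_mir_197, at log2 ratios of -0.02 and -0.56 at 12 and 24 h, and had a median of 0.25 over 2 members at 36 h. The nervous system list held only the miR-315-like novel_mir_154, at log2 ratios of -2.16, -2.61 and -2.75. No feature matched the ovary or vertebrate lists, and 0 features carried a plant name.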

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

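All tests of explanations in this part were chosen after the results were seen.

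The first pattern weighed is the 27 features higher at all 3 infected times. Of these, 7 were listed at 0 h, so absence from that list concerns the other 20. For these 20 it stays open, since only 2 had an end variant listed at 0 h, and 1 of these kept a lower bound above 2 after merging. A few groups of similar sequences may account for much of the number. At up to 5 mismatches, 14 of the 27 lay in a family, against 1 of the 77 others tested at all 3 times. At up to 4 mismatches these were 11 and 1, and at up to 6 they were 17 and 7. The 77 leave out features below the minimum count at 0 h that met it at only some infected times. Of all features called higher, 21 of 60 at 12 h, 20 of 48 at 24 h and 15 of 41 at 36 h lay in a family. Of those called lower, 1 did at each time. The contrast with the 77 therefore cannot set the 27 apart from other rising features. Infection cannot be told apart from injection, age or library, because 0 uninfected or mock-injected libraries were taken after 0 h.

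The second pattern is the fall of novel_mir_174. Its 20 nt may be a fragment of bacterial 5S ribosomal RNA: it had 1 mismatch to the start of that RNA, written from general knowledge. None of 20 shuffled references matched any feature at up to 2 mismatches. Such matches are rare by chance at this length, so the shuffled references add little. No other ribosomal RNA was compared. Infection cannot be told apart here from injection, age or library, again with 0 such control libraries.

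The third pattern is the calls of features listed at 0 in one library, 150 over the 3 comparisons with 0 h. The same RNA listed with other ends may account for part of them: 32 had an end variant listed in that library, and 22 of these calls were not kept after merging. Of the 22, 19 then met neither bound, and 3, all of novel_mir_193, turned from lower to higher. For the other 118, no variant with an identical overlap of at least 18 nt was listed there, so end variants as defined here do not account for them.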

How the results depend on the processing

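The limit to called features listed in both libraries, merged end variants, totals and shares without novel_mir_174, list medians with listed zeros set at 3 reads and correlations over features listed in all 4 libraries were chosen after seeing the data. Counts are given in this order: higher then lower for 12, 24 and 36 h against 0 h, 24 h against 12 h and 36 h against 24 h, then higher and lower at all 3 times. The reported counts were 60, 18, 48, 30, 41, 20, 14, 30, 17, 37, 27 and 15. TMM, median-of-ratios scaling, totals without the 10 most abundant features or without novel_mir_174, a CV of 0.2, rows as features and sums over families left each count within 1.5 times of these. Calls that rest on a listed 0 cannot be lost to these scalings or to a CV of 0.2. Against 0 h they were 49 of 60, 37 of 48 and 30 of 41 higher calls at 12, 24 and 36 h. Among lower calls they were 6 of 18, 17 of 30 and 11 of 20. For these the stability was fixed in advance. With a minimum of 10 counts the counts were 149, 69, 131, 67, 127, 75, 74, 64, 77, 106, 55 and 34. With no minimum the counts were 1.8e+02 (rounded), 111, 239, 67, 233, 75, 169, 64, 77, 210, 71 and 34. With a minimum of 200 counts the counts were 26, 3, 16, 10, 14, 3, 2, 9, 6, 11, 9 and 3. With a ratio of 1.5 the counts were 63, 23, 52, 37, 48, 23, 31, 37, 26, 45, 28 and 17. With a ratio of 4 the counts were 60, 10, 45, 22, 38, 16, 9, 22, 16, 17, 27 and 7. With a CV of 0.4 the counts were 60, 11, 46, 23, 38, 17, 9, 23, 16, 23, 27 and 8. With features listed in both libraries the counts were 11, 12, 11, 13, 11, 9, 7, 8, 1, 29, 7 and 7. With merged end variants the counts were 57, 15, 45, 26, 37, 14, 11, 23, 11, 34, 28 and 13. A higher minimum or ratio and the limit to listed features admit fewer features by construction. From a minimum of 10 counts to none, only calls of features higher in the smaller library grew, except for 12 h against 0 h. A listed 0 stands for 3 reads, which is more RPM in the smaller library. Low counts in the larger library therefore miss the bound against it. The cause of other changes was not tested. Pearson r for 12 and 24 h, 12 and 36 h, and 24 and 36 h was 0.68, 0.72, 0.70 with a minimum of 10 counts. Pearson r for 12 and 24 h, 12 and 36 h, and 24 and 36 h was 0.83, 0.87, 0.79 with a minimum of 200 counts. Pearson r for 12 and 24 h, 12 and 36 h, and 24 and 36 h was 0.97, 0.97, 0.97 with features listed in all 4 libraries. The percent share of lmi-miR-281-5p at 0, 12, 24 and 36 h was 71.9, 78.9, 79.8, 72.7 with predicted miRNAs left out. The percent share of lmi-miR-281-5p at 0, 12, 24 and 36 h was 42, 50.2, 48.2, 44.5 with novel_mir_174 left out. The number of fixed lists with a median above 0 at 24 h was 5, and 2 with TMM scaling, which moved log2 ratios by -0.23. Of 72 named ratios, 2 missed the size rule with TMM, 1 with median-of-ratios scaling and 6 with totals without the 10 most abundant features, and none changed direction. No paired analysis was possible because each group has 1 library and the labels give no shared replicate numbers.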

Other observations

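Among the small RNA classes in the table, rRNA made up 9.14% of the class numbers at 0 h (95% Clopper-Pearson interval 9.09 to 9.20), 6.04% at 12 h, 4.03% at 24 h and 5.32% at 36 h. The share of tRNA was 2.23% at 0 h, 1.21% at 12 h, 1.27% at 24 h and 1.29% at 36 h. Unannotated sequences made up 88.4%, 92.5%, 94.4% and 93.2% in the same order.

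The authors' target predictions paired 776 predicted miRNAs with 943 target sequences in 65809 distinct pairs. Of 527 target sequences with an annotation entry, 499 had a KEGG ortholog; 159 were cytochrome c oxidase subunit 1, 125 NADH-ubiquinone oxidoreductase chain 2, 23 glutathione S-transferase and 19 juvenile-hormone esterase. Tyrosinase, the enzyme class of insect melanin formation, was a predicted target of 16 of the 27 features higher at all 3 times, 12 of the 15 lower ones and 44 of the 60 other tested features.

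Features at 0 in 1 library with at least 50 counts in each other library numbered 20 for 0 h, 0 for 12 h, 7 for 24 h and 1 for 36 h. The 20 for 0 h are the same features as the 20 listed at 0 at 0 h among the 27 higher at all 3 times.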
